A study of Xenopus laevis with 18 samples.

How the data were processed

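Poly(A)-selected RNA was measured by sequencing in 18 whole-embryo libraries of Xenopus laevis (J strain), the African clawed frog, with 1 library for each of 18 Nieuwkoop-Faber stages, the standard numbering of Xenopus development. Per the labels' protocols, poly(A)+ RNA was captured on oligo(dT) beads and turned into libraries with a ScriptSeq kit and 10 cycles of amplification. Because selection was for the poly(A) tail, a value can move with the length of the tail as well as with the amount of RNA, which matters most in the early embryo, where tails of stored mRNAs are lengthened and shortened.

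The authors deposited 1 table of TPM (a share of all transcripts, scaled to a fixed total), holding 31357 gene models and 88 ERCC spike-in entries, which are synthetic RNAs added to a sample. CASAVA 1.8.2, Trimmomatic, Bowtie and RSEM are named in the submitters' processing notes; the role of each tool, the other versions and the genome build are not given in the sources used here. The deposited TPM of the libraries at stages 0 and 2 summed to 1000000 within rounding. In each library from stage 6 on, the decimals and the sums point to a rescaling of the spike-in entries in classes after the TPM was made, which is an inference from the values and not stated in the labels. By this reading 22 entries were divided by 0.5, 21 by 1, 22 by 0.67 and 22 by 4, and 1 entry was at 0. With these divisions undone, the sums lay between 999998.8 and 1000000.7, against up to 1010293.9 as deposited. All columns of the table were matched to a library by their stage. 6 of the 18 column names (stages 0, 20, 23, 26, 30 and 33) carry the suffix rr, which the labels do not explain.

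TPM keeps no sequencing depth, so the number of reads per library is unknown and no counting interval or floor is given. Exact zeros in such a table can be failed estimates, so a model at 0 is described as listed at 0. Reads of near-identical models cannot be told apart from this table, which matters in this tetraploid-derived genome, where many genes exist as a pair of similar copies. Measurement precision was taken from 37 spike-ins with a mean of at least 10 TPM and no zero in any library. As shares of the spike-in total of each library, their median SD over the 18 libraries was 0.31 on the log2 scale, with a range from 0.17 to 0.75. This spread holds library preparation and sequencing, but not differences between embryos. An error in the volume of spike-in added is common to all spike-ins of a library and cancels in these shares.

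The model identifiers are the authors' own; the table does not pair them with gene symbols, and 0 of them matched the reference table of names. The tests of gene lists (camera), the order of HOX gene onset and the pairs of maternal and later counterparts, all chosen before the data were examined, were therefore not run. Models are named by identifier, by the rule fixed for that case: adjusted p under 0.05, each stage of one period above each stage of the other, a mean of at least 10 TPM in the higher period (for the course over all stages, a maximum of at least 10 TPM and an absolute Spearman rho of at least 0.8), and then at most 2 models with the largest rise and 2 with the largest fall per comparison on the log2 scale. The 2 models described as on/off were chosen after their values were seen: they reached at least 1000 TPM, were at 0 in at least 10 libraries and dropped at least 2 times from 500 TPM or more to 0 between neighbouring stages.

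The stages were grouped into 5 periods before the data were examined: early (stages 0, 2, 6, 6.5 and 7), blastula (8, 8.5 and 9), gastrula (10 and 12), neurula (14, 16, 18 and 20) and tailbud (23, 26, 30 and 33). The stages of a period are different time points and not replicates; the spread within a period holds developmental change as well as error, each SD given for a period is a spread over its stages, and p-values measure differences against that spread. Nothing in the labels says whether the libraries came from 1 clutch or several. The tests, filters, thresholds and most alternatives were also set before the data were examined.

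Tests were run with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment at 0.05, two-sided. Gene models with at least 1 TPM in at least 2 libraries were tested, which left 23880; spike-ins were left out. The period means were fitted to all 18 libraries (13 residual degrees of freedom) and compared in 5 contrasts. The course over all stages was an F-test of a natural spline with 3 degrees of freedom over stage order, with the direction taken from Spearman's rho. The trend within the early period was a linear term over its 5 libraries (3 residual degrees of freedom). Changes are differences on the log2(TPM + 1) scale, which understates changes of low models. Steps between neighbouring stages were described without a test for models with a mean of at least 10 TPM, as log2 differences centred on their median and set beside the same differences of the 37 spike-ins. Other summaries used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

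The fits were tested on simulated data with 200 of 23880 models changed. Recovery is a share of these 200 models. It is not shown to hold for low models, or for libraries that differ in scale as the real ones did. A change of 4 on the log2 scale was recovered in 98% of models for gastrula minus blastula and for neurula minus gastrula, 99% for blastula minus early, for tailbud minus neurula and for the stage course, 100% for tailbud minus early, and 59% for the early trend. A change of 2 was recovered in 75.5% of models for blastula minus early, 47.5% for gastrula minus blastula, 56% for neurula minus gastrula, 80% for tailbud minus neurula, 84.5% for tailbud minus early, 38% for the stage course and 0% for the early trend. A change of 1 was recovered in 0% of models in each of these 7 fits. At a change of 4, the share of false calls was highest for blastula minus early, at 7%, and lowest for the early trend, at 3.3%.

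Alternatives were pseudocounts of 0.1 and 10, no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, limma without the trend, other splines, other borders of the periods, fits with only the compared periods, and leaving out each library in turn. After the data were seen, scaling to the spike-ins, rescaling without the spike-ins and the on/off models, leaving out the 5 libraries in which those models were on, and fits restricted by the rr suffix were added.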

Results

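The dataset followed poly(A)+ RNA through frog development, from stage 0, the start of development, to stage 33, in a series whose title concerns how mRNA and protein change together in the vertebrate embryo. Each of 18 stages was sampled by 1 library, so no stage was replicated. The stages were grouped into the early period before the mid-blastula transition, at which the embryo's own genome becomes broadly active (n = 5), and the blastula (n = 3), gastrula (n = 2), neurula (n = 4) and tailbud (n = 4) periods. Values are TPM of gene models known by identifier only, and sequencing depth is unknown.

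The number of gene models at 1 TPM or more was 15297 at stage 0 and 21158 at stage 33. By period it averaged 16204 ± 817 early (SD over stages, n = 5), 17159 ± 229 in the blastula (n = 3), 16126 ± 98.3 in the gastrula (n = 2), 17925 ± 943 in the neurula (n = 4) and 20700 ± 416 in the tailbud (n = 4). Models listed at 0 numbered 10966 at stage 0, 9322 at stage 18, 6491 at stage 20 and 3277 at stage 33; stage 20 is also the first after stage 0 whose column carries the suffix rr. Spike-in RNAs made up 11.2% of the total TPM at stage 0 and 1.49% at stage 33; the amount added per sample is not given in the sources used here.

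**Figure D1:**
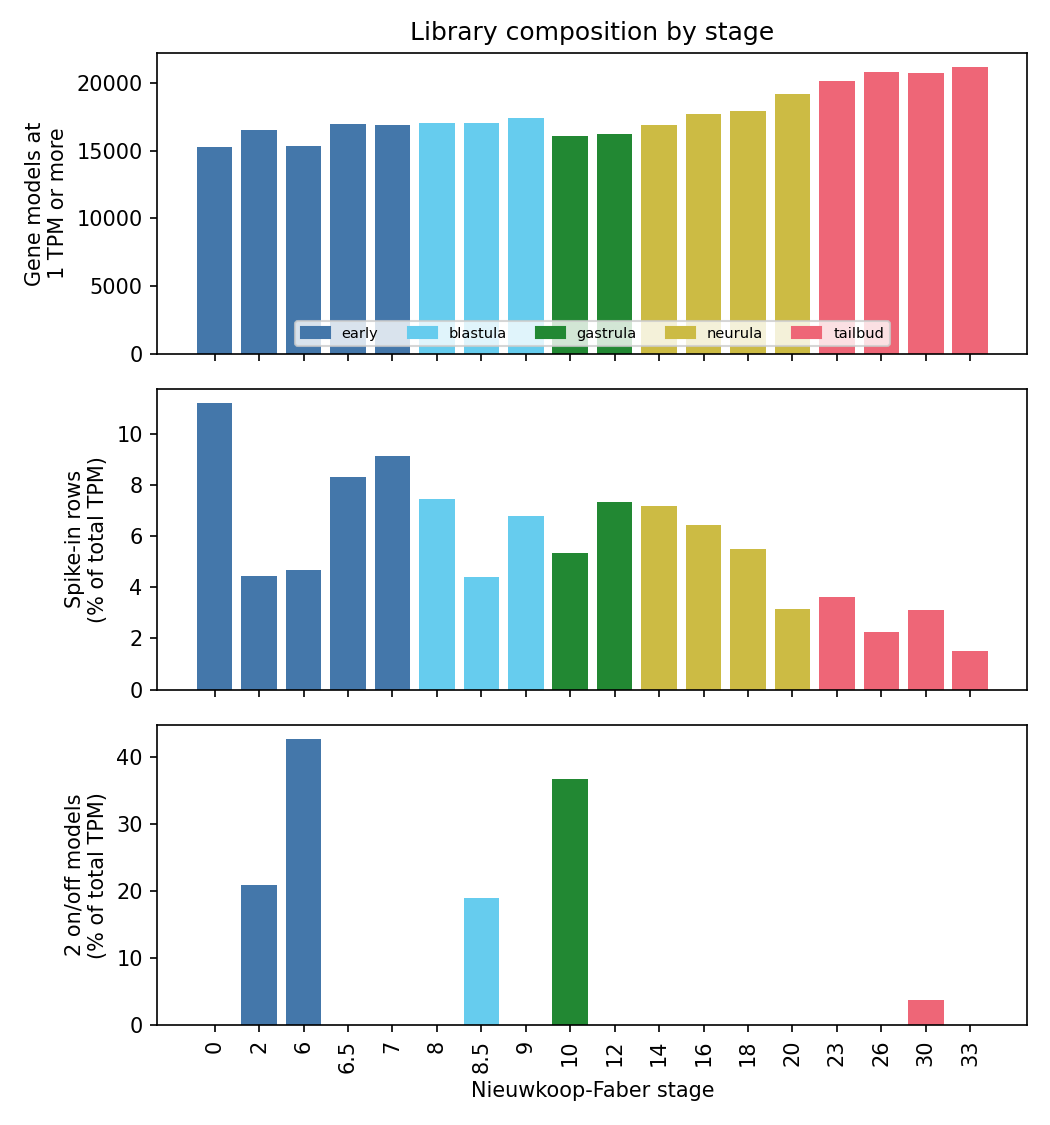
Bars give, for each of the 18 stages on the horizontal axis, the number of gene models at 1 TPM or more, the percent of total TPM in spike-in entries and the percent in the 2 on/off models, coloured by period. The 2 on/off models held 42.69% of the total at stage 6 and 0% in 13 libraries.

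A pair of gene models was on in some libraries and off in their neighbours. XeXenL6RMv10031603m stood at 207302 TPM at stage 2, 425725 at stage 6, 186571 at stage 8.5, 362793 at stage 10 and 37595 at stage 30, and was listed at 0 in the other 13 libraries. XeXenL6RMv10023270m was above 0 in the same 5 libraries, at 798 to 6170 TPM, and listed at 0 in the rest. TPM is a share, so the remaining models of those 5 libraries are lower by that share: the pair held 36.8% of the total at stage 10 and 19.0% at stage 8.5. Contrasts are therefore given with the scaling as deposited and, where the direction of the calls turned on it, under scalings that centre the libraries.

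Neighbouring libraries differed most between the onset and the end of gastrulation. The stage numbers are unevenly spaced, so steps between neighbours cover unequal intervals and their sizes are not rates. Spearman's rho between neighbouring libraries, across gene models, was lowest at 0.812 from stage 10 to stage 12 and highest at 0.979 from stage 7 to stage 8. Of 11005 models with a mean of at least 10 TPM, 4324 (39.3%) differed by more than 2-fold between stages 10 and 12 after centring, 2229 upward and 2095 downward, while 0 of the 37 spike-ins did. The steps on either side were also large: 2150 models (19.5%) from stage 9 to 10, with 0 spike-ins, and 1970 (17.9%) from stage 12 to 14, with 1 spike-in. From stage 6.5 to 7 and from stage 7 to 8 the share was 1.6% and 1.3%. From stage 26 to 30, 4.8% of the models but also 5 of the 37 spike-ins passed 2-fold, so that step did not exceed the spike-in error. The same held for smaller steps: 1.29% of models against 2.7% of spike-ins from stage 7 to 8 and 2.45% against 5.41% from stage 8 to 8.5. It was 2.06% against 2.7% from stage 23 to 26 and 2.43% against 8.11% from stage 30 to 33. The spike-ins were above 0 in each library, whereas a model chosen by its mean can lie near 0 at a compared stage. For such models the spike-ins can understate the error.

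**Figure D2:**
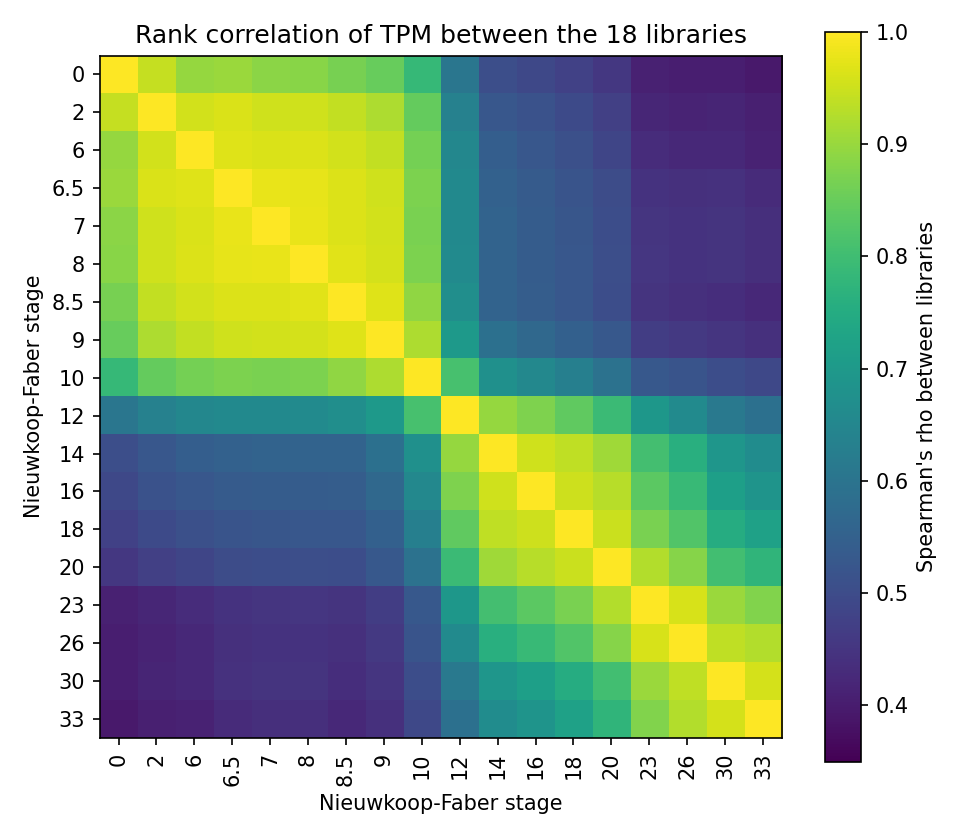
Colour gives Spearman's rho, across gene models, between the TPM of each pair of the 18 libraries, with Nieuwkoop-Faber stage on both axes. Libraries up to stage 9 form a block of high correlation, stage 10 lies beside it, and stage 0 against stage 33 reaches 0.394.

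**Figure D3:**
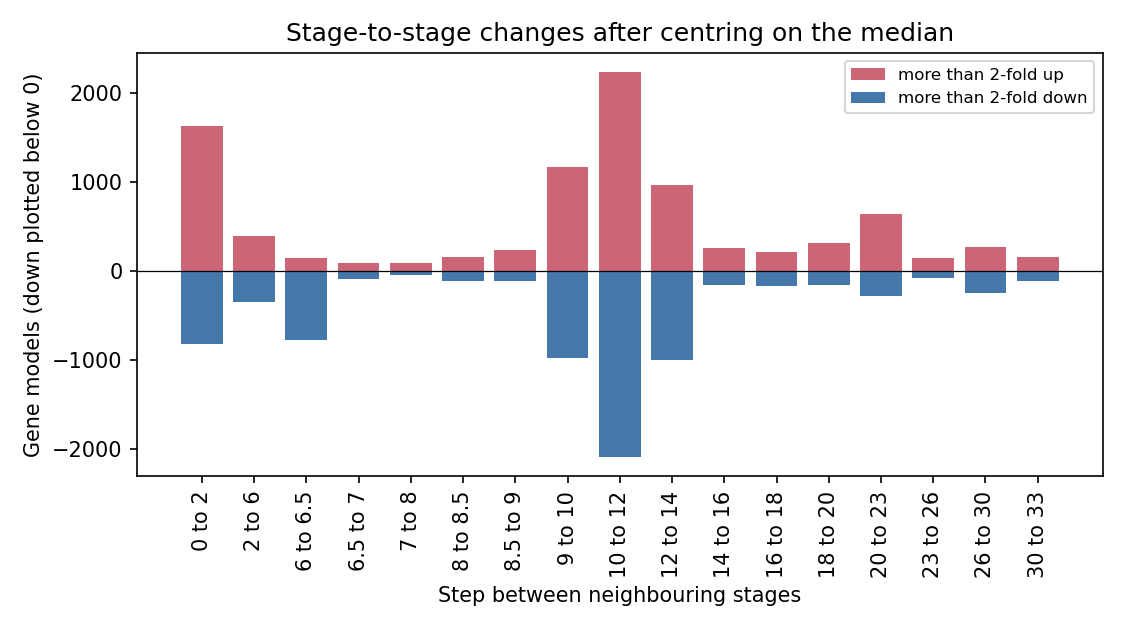
Bars give the number of gene models, of 11005 with a mean of at least 10 TPM, that differed by more than 2-fold upward (above 0) or downward (below 0) between neighbouring stages, after centring on the median. The step from stage 10 to stage 12 is the tallest in both directions, with 2229 and 2095 models.

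Most gene models changed over the 18 stages. In the spline test 20522 of 23880 models passed, 10551 of them with a rising and 9969 with a falling rank order over stages. XeXenL6RMv10033308m was listed at 0 in each library up to stage 14, stood at 139 TPM at stage 16 and reached 1802 TPM at stage 26 (rho = 0.87, limma adjusted p = 4.01e-09). XeXenL6RMv10003671m passed as well (rho = 0.81, limma adjusted p = 6.41e-05), with 1360 ± 267 TPM in the tailbud (n = 4), but moved between 0 and 97.8 TPM among the early libraries. XeXenL6RMv10016014m fell from 2474 TPM at stage 0 to 401 at stage 10 and was listed at 0 from stage 12 on (rho = -0.91, limma adjusted p = 2.59e-10). XeXenL6RMv10046028m fell from 2039 TPM at stage 0 to 43.3 at stage 10 and 1.77 at stage 12 (rho = -0.87, limma adjusted p = 3.07e-09). As deposited, the period with the highest mean was the blastula for 9684 models (40.6%), the tailbud for 6868 (28.8%), the neurula for 3770, the early period for 2640 and the gastrula for 918. This order depended on the scaling: after median-of-ratios scaling the counts were 3027 (12.7%), 8322 (34.8%), 4931, 4638 and 2962 for the same periods. The rising models were 51.4% of those called as deposited, 77.3% with the TPM scaled to the spike-ins, 62.4% with median-of-ratios scaling, 46.8% after rescaling without the on/off models and 46.0% with quantile normalization. As deposited but with a filter of 5 TPM they were 44.1%, so the balance also depended on whether low models were tested.

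Before the mid-blastula transition, where poly(A)+ RNA can change without transcription, no steady trend passed. In the linear test over the 5 early stages limma called 0 of 23880 models, with 4350 at an unadjusted p under 0.05, and the fit recovered 0% of simulated changes of 2 on the log2 scale. Steps between neighbouring early stages differed in size. From stage 2 to 6, 736 models (6.7%) passed 2-fold, with 2 of 37 spike-ins (5.4%), so this step barely exceeded the spike-in error. By the reading given earlier, the rescaling of the spike-ins also starts at stage 6, so a difference in handling cannot be told apart from stage at this step. From stage 6 to 6.5, 923 models (8.4%) passed 2-fold, 144 upward and 779 downward, with 0 spike-ins. The largest early step was from stage 0 to stage 2: 1627 models were more than 2-fold higher at stage 2 and 829 more than 2-fold lower, together 22.3% of 11005, with 0 of 37 spike-ins past 2-fold. For models near 0 at stage 0 the spike-ins can understate the error, as above. The models that were higher at stage 2 had a median of 5.4 TPM at stage 0, 20.3 at stage 2 and 38.1 at stage 7. Those that were lower had medians of 132.1, 64.8 and 60.8 TPM. From stage 2 to stage 7, 1355 of the 1627 and 700 of the 829 stayed within 2-fold, and 17 and 33 moved back by more than 2-fold. The step from stage 0 to stage 2 rests on 1 library on either side and has no replicate check. Stage 0 is also the only early library with the suffix rr. Its 5th percentile of the values above 0 was 0.09 TPM, against 0.28 at stage 2, and its models at 0 numbered 10966, against 12234. The likeness of stages 2 and 7 does not separate a change in the embryo from a library that stands apart.

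Around the mid-blastula transition few models passed against the earlier stages, in a test that recovered 0% of simulated changes of 1 on the log2 scale. The contrast of the blastula (stages 8, 8.5 and 9) with the early period called 6 models, each higher in the blastula, with 5079 at an unadjusted p under 0.05. XeXenL6RMv10025907m, the model that met the naming rule, stood at 12.4 ± 2.88 TPM in the blastula (SD over stages, n = 3) against 1.59 ± 1.81 early (n = 5). The rise was 2.55 ± 0.39 (SE) on the log2 scale (limma adjusted p = 0.0202), and the model was listed at 0 from stage 12 on. The count depended on single libraries: it was 2348 without stage 7, 145 without stage 8, 15 without stage 6.5, 3 without stage 8.5 and 0 without stage 0. It was 0 under median-of-ratios scaling and 3 higher with 2 lower under quantile normalization, and the call of XeXenL6RMv10025907m was lost in 14 of 32 alternatives (limma adjusted p from 0.000366 to 0.499). In those 14 its rise remained between 1.59 and 3.36 on the log2 scale.

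At gastrulation 9332 gene models passed as deposited, and the 2 gastrula stages differed from each other. Of these models, 3759 also passed under median-of-ratios scaling and 4235 under quantile normalization. As deposited, 1305 models were higher in the gastrula than in the blastula and 8027 lower, of which 728 and 3109 changed more than 4-fold. XeXenL6RMv10040861m rose from 7.01 ± 11.4 TPM in the blastula (n = 3) to 189 TPM at stage 10 and 2078 TPM at stage 12, a change of 7.52 ± 1.11 (SE) on the log2 scale (limma adjusted p = 8.93e-05). XeXenL6RMv10003662m rose by 7.10 ± 0.67 (limma adjusted p = 2.04e-06), from 8.31 TPM at stage 9 to 153 at stage 10 and 1123 at stage 12. XeXenL6RMv10046028m fell by 6.36 ± 0.90 (limma adjusted p = 6.65e-05) and XeXenL6RMv10000530m fell by 6.24 ± 1.01 (limma adjusted p = 0.000173), the latter from 823 TPM at stage 9 to 79.3 at stage 10 and 0.86 at stage 12. The direction of the calls turned on the scaling: the median over all models was -0.66 as deposited and 14.0% of the calls were higher, while median-of-ratios scaling called 3421 higher and 2498 lower and quantile normalization 2577 and 3075. Rescaling without the on/off models, with 1678 and 6918, and spike-in scaling, with 868 and 6513, kept the deposited balance. Without stage 10 the higher and lower calls were 2374 and 7082, with stage 10 counted as blastula 2177 and 4139. Without stage 12 the count was 3487. In a fit of the 5 libraries alone XeXenL6RMv10040861m and XeXenL6RMv10000530m kept their changes of 7.52 and -6.24 but, with fewer residual degrees of freedom, not their calls (adjusted p = 0.0547 and 0.0695, the highest of 32 alternatives, whose lowest were 7.36e-06 and 4.42e-07).

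**Figure D4:**
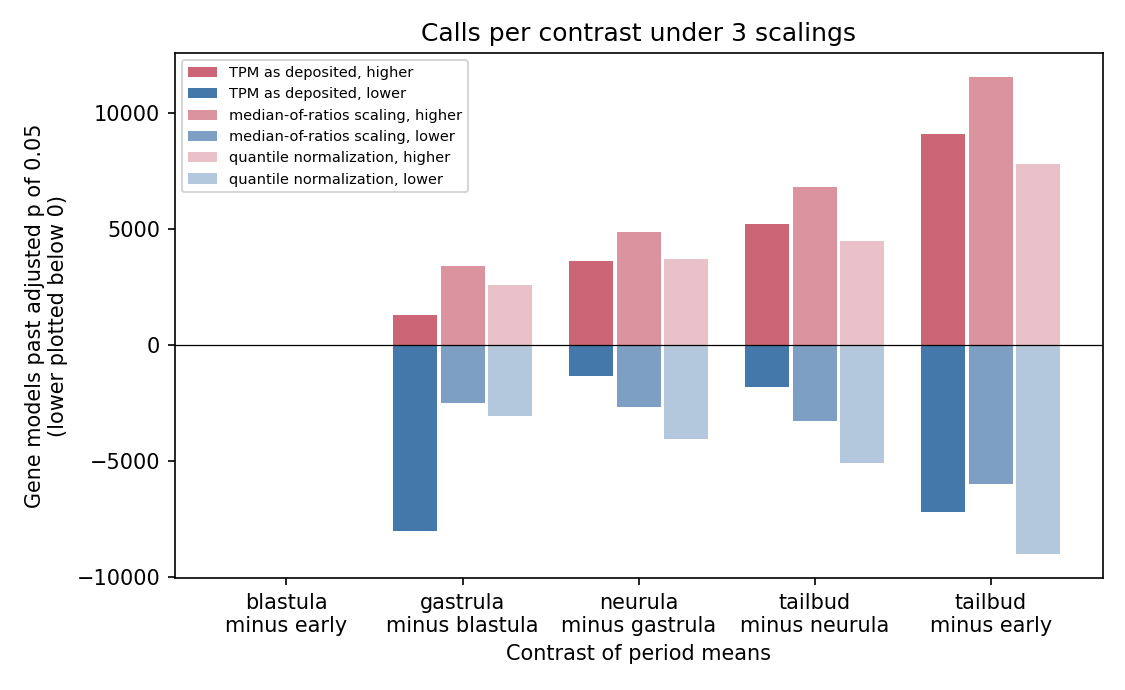
Bars give the number of gene models past an adjusted p of 0.05 that were higher (above 0) or lower (below 0) in the first-named period of each of 5 contrasts, with TPM as deposited, after median-of-ratios scaling and after quantile normalization. For gastrula minus blastula the higher calls number 1305, 3421 and 2577 and the lower calls 8027, 2498 and 3075.

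From the gastrula to the neurula, when the neural plate forms and closes, more models rose than fell as deposited. Of 4989 models that passed, 3642 were higher in the neurula and 1347 lower, of which 1388 and 462 changed more than 4-fold. XeXenL6RMv10013764m was listed at 0 from stage 2 to stage 12 and stood at 106 TPM at stage 14 and 690 at stage 20 (limma adjusted p = 8.86e-08). XeXenL6RMv10030191m rose by 7.85 ± 0.68 on the log2 scale (limma adjusted p = 2.1e-07), from 0.24 TPM at stage 12 to 89.5 at stage 14 and 762 at stage 20. XeXenL6RMv10018740m fell by 5.92 ± 0.96 (limma adjusted p = 0.000205): it stood at 260 TPM at stage 9, 453 at stage 10, 218 at stage 12 and 18.8 at stage 14. XeXenL6RMv10024162m passed too (limma adjusted p = 0.0249), being listed at 0 in the 4 neurula libraries against 27.7 TPM at stage 10 and 118 at stage 12. However, it was also at 0 in 4 earlier libraries, and in the tailbud it was back at 74.3 ± 30.5 TPM (n = 4), beside a gastrula mean of 73. Its call was lost in 8 of 31 alternatives, those without either gastrula stage among them (limma adjusted p from 0.00857 to 0.144), while the difference kept its direction in all 31. Scaling changed the balance: median-of-ratios called 4873 higher and 2665 lower, quantile normalization 3706 and 4042, rescaling without the on/off models 3405 and 2714, and spike-in scaling 4149 and 422. Without the 5 libraries in which the on/off models were on, which leaves 1 gastrula library, XeXenL6RMv10018740m kept a change of -5.39 but not its call (adjusted p = 0.0672, against 5.91e-05 at the lowest of 31 alternatives). Without stage 10 the count was 1325, and in a fit of these 2 periods alone 1800.

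Between the neurula and the tailbud, as organs differentiate, 7024 models passed, 5222 higher and 1802 lower in the tailbud, of which 1174 and 329 changed more than 4-fold. XeXenL6RMv10043094m was listed at 0 at stages 14, 16 and 18, stood at 4.7 TPM at stage 20 and reached 1170 TPM at stage 33, a rise of 8.30 ± 0.57 (SE) on the log2 scale (limma adjusted p = 2.01e-09). XeXenL6RMv10032947m rose by 8.10 ± 0.75 (limma adjusted p = 1.03e-07), from 0.24 TPM at stage 20 to 30.3 at stage 23 and 1635 at stage 33. XeXenL6RMv10041136m fell by 6.55 ± 0.71 (limma adjusted p = 8.8e-07), from 147 ± 93.7 TPM in the neurula to 0.33 ± 0.502 in the tailbud (n = 4 each). XeXenL6RMv10013285m fell by 5.94 ± 0.91 (limma adjusted p = 4.89e-05), from 500 ± 188 to 13.4 ± 15.5 TPM. Median-of-ratios scaling, with 6820 higher and 3261 lower, and rescaling without the on/off models, with 5467 and 2653, also called more models higher than lower. Quantile normalization called 4504 higher and 5086 lower, and spike-in scaling 14858 and 444, with a median over all models of 1.11. With only the libraries whose columns carry the suffix rr, which leaves stage 20 as the one neurula library, 8 models passed. The 4 named models kept changes of 6.42, 7.87, -4.84 and -4.86 on the log2 scale but not their calls (adjusted p = 0.0852, 0.134, 0.058 and 0.178 in the order named, the highest of 30 alternatives, whose lowest were 3.37e-10, 1.51e-10, 3.11e-08 and 4.05e-06).

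The ends of the course differed most. Between the tailbud and the early period 16272 of 23880 models (68.1%) passed, 9087 higher and 7185 lower, and 4047 and 2534 changed more than 4-fold. XeXenL6RMv10030903m rose by 11.81 ± 0.81 (SE) on the log2 scale (limma adjusted p = 2.01e-10) to 6140 ± 1080 TPM in the tailbud (n = 4), and XeXenL6RMv10040844m rose by 11.53 ± 0.91 (limma adjusted p = 1.42e-09) to 4930 ± 642 TPM. Both were listed at 0 at stages 2, 6, 6.5 and 7 but stood at 12.8 and 11.6 TPM at stage 0. XeXenL6RMv10016014m stood at 1670 ± 539 TPM early (n = 5) and was listed at 0 in the 4 tailbud libraries (limma adjusted p = 7.69e-09), and XeXenL6RMv10035758m fell by 9.11 ± 0.69 (limma adjusted p = 8.33e-10), from 1420 ± 719 to 1.88 ± 2.29 TPM. Of the 10492 models with an early mean of at least 10 TPM, 5468 were called lower in the tailbud, 1447 higher and 3577 did not pass; 1008 (9.6%) had a tailbud mean under 0.1 of the early mean and 3900 (37.2%) lay within 2-fold. Models called lower in the tailbud held 60.6% of the gene-model TPM, without the on/off pair, at stage 0, 49.3% at stage 10, 27.8% at stage 12 and 8.6% at stage 33, while those called higher held 14.4%, 21.5%, 42.3% and 73.0%. These shares follow models picked by the same libraries. The balance of the calls turned on the scaling and on the filter. The higher calls were 55.8% as deposited, 89.3% with spike-in scaling, 65.9% with median-of-ratios scaling, 50.1% after rescaling without the on/off models and 46.3% with quantile normalization. As deposited but with a filter of 5 TPM they were 47.1%, with 5961 higher and 6703 lower. The excess of higher calls as deposited thus rested on low models. Each tailbud library carries the suffix rr, while of the early libraries only stage 0 does.

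**Figure D5:**
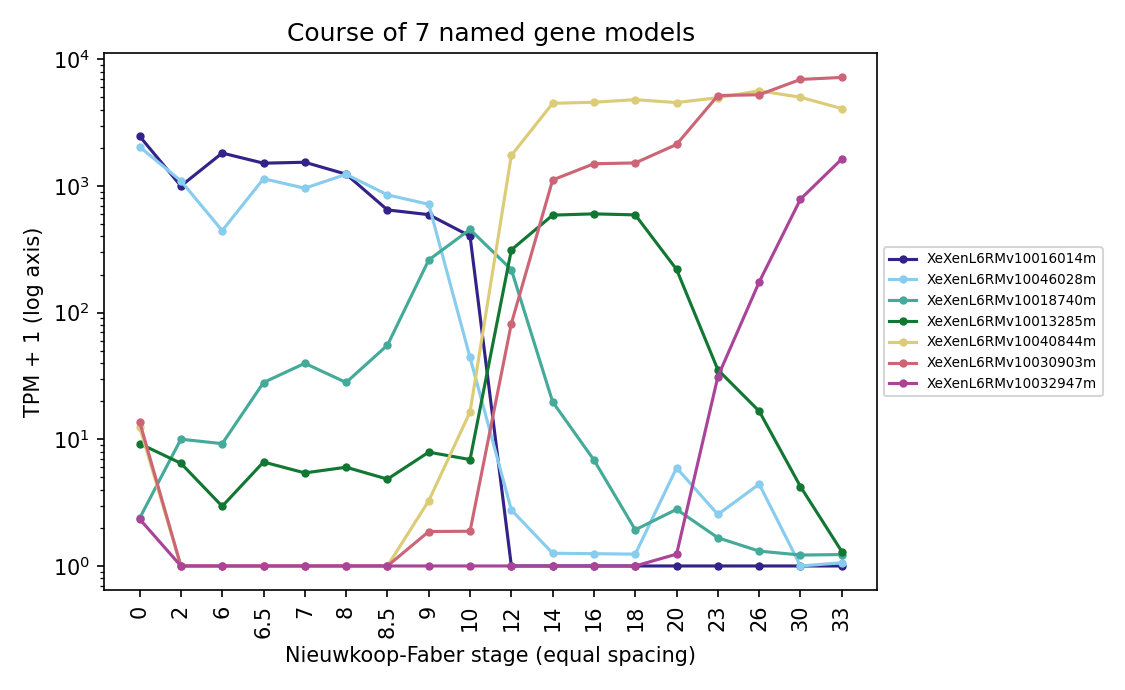
Lines give TPM + 1 on a log axis for 7 named gene models at each of the 18 stages, drawn at equal spacing. XeXenL6RMv10016014m and XeXenL6RMv10046028m drop between stages 9 and 12, XeXenL6RMv10018740m is highest at stage 10 with 453 TPM, and XeXenL6RMv10032947m climbs from stage 23 on to 1635 TPM at stage 33.

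Among the stages sampled, models low in the early stages appeared most often at stage 12, late in gastrulation. The stage numbers are unevenly spaced, with none sampled between 10 and 12, so counts per stage are not rates. Onset was scored in 3612 models with an early median under 0.5 TPM and a maximum of at least 5 TPM. It was the first stage from stage 8 on at 1 TPM or more, held in the next stage. Stage 33, the last, has no next stage, and its 31 onsets rest on that stage alone. Onset was scored on the TPM as deposited and under no other scaling. At stage 10 the on/off pair held 36.8% of the total, and the median shift of the models from stage 9 was -1.06 on the log2 scale. This can move onsets from stages 9 and 10 to stage 12. The onset was stage 12 for 874 (24.2%) and stage 14 for 587 (16.3%). It was stage 8 for 73, stage 8.5 for 150, stage 9 for 244 and stage 10 for 267. By period, onset fell in the blastula for 467 models, the gastrula for 1141, the neurula for 1312 and the tailbud for 607, and 85 met no onset. With an onset at 0.5 or 2 TPM, stage 12 was again the most frequent, with 883 and 774 models. The blastula counts moved with the threshold: stage 8 had 166 and 29 models, and stage 8.5 had 213 and 95. Models that rose at 1 step and fell at the next were few as deposited. Of these, 78 rose into the gastrula and fell into the neurula, 65 of them with a gastrula mean at least 4 times both the early and the tailbud mean. Another 364 rose into the neurula and fell into the tailbud, 118 of them at least 4 times. A further 336 rose into the gastrula, did not pass at the neurula step and fell into the tailbud. Models that fell into the gastrula and rose in a later period numbered 1525, some of which are among the 364; the count of falls into the gastrula depends on the scaling, as above.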

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

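The tests in this part, the counts of splits included, were written down after the results were seen; the rule for distant libraries was set beforehand. Of 36 groups of 4 or 5 libraries examined, 8 held a library far from the others. A chance rate of about 1 in 20 cannot be set against this count. Where all other libraries share the same value, the rule flags any value that differs, however small. This held for the on/off pair in the tailbud, and for XeXenL6RMv10043094m and XeXenL6RMv10032947m in the neurula, the latter flagged at 0.24 TPM. It also held for XeXenL6RMv10030903m and XeXenL6RMv10040844m in the early period. Because the stages of a period are ordered in time, a late or early stage can also stand apart through development alone.

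The pair of on/off models made 3.82% of the total at stage 30, while the other tailbud libraries held 0%. The 10 highest models other than the pair made 41.06% of the remaining TPM at stage 6, the highest in the early period, with XeXenL6RMv10008034m at 108526 TPM against 33064 at stage 6.5 and XeXenL6RMv10023271m at 91498 against 35425, both singled out after their values were seen. RNA of another cell type could bring many models into the same libraries. In the count made, 2 models of at least 5 TPM followed these 5 libraries, namely the pair itself. A model was counted only if it was at 0 in nearly all of the other 13 libraries. Models of another cell type that were also above 0 at other stages would be missed, so the count does not decide against this explanation. The pair made 8 steps between 0 and at least 500 TPM in 17 steps of the course, but it was chosen for such steps, so this does not decide against regulation by stage, which stays open. An estimate that fails for these models in some libraries, or 1 abundant RNA present in some libraries alone, cannot be told apart: 0 values of the pair lay between 0 and 500 TPM, which any of these would give, and the lengths of the models were not used here.

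XeXenL6RMv10030903m and XeXenL6RMv10040844m, abundant in the tailbud, stood at 12.76 and 11.55 TPM at stage 0, far above the other early libraries at 0. The same held for a class: of 142 models with a tailbud mean of at least 100 TPM and a mean under 0.1 TPM over stages 2 to 7, 120 were above 0 at stage 0, against 13 at stage 8 and 22 at stage 8.5, which like stage 0 were not used to choose them, at a median of 0.201% of the tailbud mean (quartiles 0.116 and 0.292), and across these models the stage 0 value followed stage 26, the highest of 17 stages, with a Spearman rho of 0.72, beside 0.71 for stage 23, 0.62 for stage 30 and 0.58 for stage 20 (for stage 26, permutation p = 1e-05 with no allowance for picking the highest, the smallest that 100000 resamples can give; genes are not independent replicates). Carry-over of RNA or reads from a later library is a candidate explanation, as it needs such a relation. For depth alone, models at 1 to 5 TPM at stage 0 were compared, whatever their other early values. Of 77 with a tailbud mean of at least 100 TPM, 55.8% were above 0 at stage 2 (95% Wilson interval 44.7 to 66.4). Of 658 with a tailbud mean under 1 TPM, 90.6% were above 0 there (88.1 to 92.6), a difference of -34.8 points. At equal TPM a shorter model yields fewer reads, and the classes were not matched for length. The difference goes against depth alone only if the classes are alike in length, which is not known here. RNA present in the egg that loses its tail by stage 2 stays open. In the other direction, 19 models with an early mean of at least 100 TPM and a mean under 0.3 TPM over stages 14 and 16 were examined: 14 were higher at stage 20 than at stage 18, and 11, 12, 8 and 11 at stages 23, 26, 30 and 33. This leaves carry-over from stage 0 undecided, because the choice by low neurula values and the lower floor of these libraries could give it too.

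Stage 20 stood apart within the neurula for the named models of the last step: XeXenL6RMv10043094m was highest there at 4.7 TPM, XeXenL6RMv10032947m highest at 0.24 TPM, and XeXenL6RMv10013285m lowest at 218.46 TPM. It is also the library at which the number of models at 0 dropped from 9322 to 6491. Of the 3449 models at 0 at stage 18 and above 0 at stage 20, 579 were at 1 TPM or more and the median was 0.3 TPM, beside a 5th percentile of 0.26 TPM among the values above 0 at stage 18. Greater depth and onset of transcription at stage 20 cannot be told apart from these values, because the median lies just above the lowest values of stage 18 and depth is unknown; stage 20 is the last neurula stage as well as the only one with the suffix rr.

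XeXenL6RMv10025907m was highest within the early period at stage 6.5, with 4.79 TPM against 1.02 at stage 7.

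Other splits of the libraries were counted for the contrasts of periods with at least 3 libraries each. For tailbud minus neurula 1 of 35 splits, the real one, gave as many as 7024 calls, and the highest other gave 1815. For tailbud minus early 1 of 100 drawn splits gave as many as 16272, with 14394 as the highest other, which moved only stage 6 across. For the stage course 1 of 100 orders gave as many as 20522, with 9299 as the highest other. In each of these the real grouping or order gave the most calls. Because the stages are ordered in time and cannot be exchanged freely, this gives no probability of chance and does not exclude it. For blastula minus early 2 of 56 splits gave 6 calls or more, and the highest other gave 8786 by setting stages 0, 2 and 6 against the other early and blastula stages. That split called 5003 after rescaling without the on/off models and 1163 under median-of-ratios scaling, where the real one called 6 and 0, so it points to a structure of these 8 libraries that is partly, and not wholly, one of scaling. By the reading given earlier, the spike-ins were rescaled from stage 6 on and not at stages 0 and 2. A difference in the handling of those libraries therefore cannot be told apart from stage here. For the early trend the real count of 0 is met by all 60 orders by definition, so the comparison decides nothing; the highest was 2997, with stages 2 and 6 exchanged, and 0 under median-of-ratios scaling, which removes the low level of the remaining models at stage 6.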

How the results depend on the processing

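The spike-in scaling, the rescaling without the on/off models, the fit without the 5 libraries in which they were on and the fits by suffix were chosen after seeing the data. Across 647 alternative values of the 21 named results none changed direction, 618 kept their side of the threshold and 29 lost the call. The named models were picked from these same libraries for the largest changes that passed. A kept direction was therefore nearly given in advance and says little about other models. The stage course, the early trend and tailbud minus early kept their counts within 1.5 times under each alternative run. Leaving out 1 library at a time gave 19278 to 21073 calls for the stage course, 0 to 0 for the early trend, 0 to 2348 for blastula minus early, 3487 to 10311 for gastrula minus blastula, 1325 to 6515 for neurula minus gastrula, 4940 to 8200 for tailbud minus neurula and 14995 to 16810 for tailbud minus early. Where a period kept 1 library, it was assumed to vary like the others. The 6 calls of blastula minus early became 44 with a pseudocount of 10, 13 without a filter, 148 with stage 8 counted as early and 2 with spike-in scaling. They became 0 with a filter of 5 TPM, with median-of-ratios scaling, without the trend, with stage 10 counted as blastula and with only the columns without the suffix rr. Gastrula minus blastula gave 5919 calls with median-of-ratios scaling and 5652 with quantile normalization, against 9332. Neurula minus gastrula, at 4989, gave 7538 and 7748 under these scalings, 1087 with stage 10 counted as blastula, 1800 with only the 2 periods and 1065 without the 5 libraries; in the last and in the count of 1087 the gastrula is 1 library. Tailbud minus neurula, at 7024, gave 4560 with a filter of 5 TPM, where fewer models are tested, 10918 with only the 2 periods, 15302 with spike-in scaling and 8 with only the columns with the suffix rr. The cause was not tested for the other changes. The replicate numbers of the periods only name stages. No paired analysis was possible because each library is a different stage. Gene lists, HOX onset and counterpart pairs were not run, as the models carry no gene symbols. Depth is unknown, so no limit from it can be set for low models.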

Other observations

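The test in the last paragraph was chosen after the data were seen, and the values before it belong to no planned comparison.

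All 27 combinations of rise, fall and no call over the 3 later steps occurred. As deposited, 5807 models (24.3%) fell into the gastrula and passed in neither later step, 3164 (13.2%) rose only into the tailbud, 1820 (7.6%) rose only into the neurula, and 443 (1.9%) rose into the gastrula and passed in neither later step. Whatever the remaining step did, 812 rose into the neurula and again into the tailbud and 1162 fell into the gastrula and rose into the tailbud, and 17 rose at each of the 3 steps. No step passed for 7205 models (30.2%). A model that passed at one step and not at another is not shown to differ between them, and the falls into the gastrula depend on the scaling.

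The ratio of gene-model TPM to spike-in TPM, without the on/off pair, was 7.91 at stage 0, 16.8 at stage 2, 9.92 at stage 7, 17.1 at stage 18, 30.8 at stage 20, 29.8 at stage 30 and 65.9 at stage 33. By period it was 11.4 ± 3.31 early (SD over stages, n = 5), 14.5 ± 2.53 in the blastula (n = 3), 11.7 ± 1.27 in the gastrula (n = 2), 18.8 ± 8.15 in the neurula (n = 4) and 41.6 ± 17.9 in the tailbud (n = 4). The amount of spike-in and of embryo RNA per library is not given in the sources used here, so this ratio is no measure of RNA per embryo.

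The classes by which the spike-ins had been rescaled moved apart before and together after that rescaling. With it undone, the median log2 ratio of the later libraries to those at stages 0 and 2 was -1.79 for the class divided by 0.5, -1.32 for 0.67, -0.67 for 1 and 1.24 for 4. As deposited, the same medians were -0.79, -0.75, -0.67 and -0.76.

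A hypothesis was that models gaining poly(A)+ RNA after stage 0 are those lost by stage 12. Over 9472 models with a mean of at least 10 TPM, in all libraries and in the early period, the change from stage 0 to stage 2 and the change from stages 8 and 9 to stage 12, which share no library, had a Spearman rho of -0.13 (permutation p = 1e-05, the smallest that 100000 resamples can give; genes are not independent replicates). Within the lowest, middle and highest models by level at stage 7, rho was -0.09, -0.08 and -0.15. The bar written for the hypothesis was a rho under -0.1, which the whole set and the highest models met and the lowest and middle models did not. The relation is weak, was tested once, in 1 library per stage, and uses the stage 0 library, whose floor differs from the others, so the hypothesis stays open.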
